A study of Homo sapiens with 4 samples.

How the data were processed

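DEK ChIP-seq was deposited for 3 libraries of MCF7 A-DCCs, precipitated with a DEK antibody, and 1 input DNA library was sequenced beside them. Per the labels' protocols, nuclei were sonicated, complexes of histones and DNA were isolated with the antibody, and adapter-ligated, PCR-amplified fragments were sequenced on an Illumina instrument. CASAVA 1.8, BWA 0.7.12-r1039 and MACS2 2.1.0 are named with build hg18, per the submitters' processing notes. The peak threshold, the rule that joined peaks to genes, the gene annotation and the use of the input library are not given in the sources used here. Each such choice sets how many genes a list holds, and a rule that assigns a peak to every gene in a window would list neighbouring genes together.

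The values the authors deposited are 1 list per library, with an Ensembl gene identifier and the text of its best Swiss-Prot protein match with an E-value. A gene is present or absent, so the lists carry no read counts, depth, peak number, position, width or score. Lists were made for each library, not for pooled libraries. The exact 95% interval of a share of listed genes covers the counting error from the number of genes only. It leaves out the differences between libraries. P-values for gene lists, gene families and chromosomes compare genes with other genes. Genes that neighbour each other are not independent, so these p-values can be too small and the intervals too narrow. The p-values also do not measure the spread between cultures.

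Overlap between libraries was counted on identifiers. For lists and chromosomes, identifiers received the gene symbol in their match text if the match was a human protein, which 7105 of 10619 identifiers had. Symbols were brought up to date with RefSeq names of assembly GRCh38.p14, and 6503 of these identifiers (91.5%) reached 1 of the 20056 protein-coding symbols used as background. No table paired the identifiers themselves with symbols, so names rest on sequence similarity: pseudogenes and antisense transcripts can carry a parent gene's name, and 436 symbols were carried by several identifiers. Chromosome, gene length and gene order were taken from the same assembly by symbol and were used as groupings and ranks only, because the build named by the submitters differs from it. That build is itself in doubt, since some listed identifiers carry higher numbers than gene annotations of the time of hg18 held. Of the background, 665 provisional symbols cannot be named by such matches; the background without them was tried as an alternative.

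A symbol counted as listed when at least 2 of 3 libraries listed it. Where several identifiers carried a symbol, any of them sufficed in each library, so different identifiers could supply different libraries. The 24 gene lists, with 977 of 978 members in the background, the tests and the listing rule were fixed before the data were examined. The naming rule was not. List results were seen first with human matches only, then with matches to other organisms as well, and the human-only rule was then taken up again, out of concern that the wider rule names copies after a parent gene, which was not tested. Results are given under the human-only rule, and under the wider rule for some lists and genes only.

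Each list was compared with all other symbols by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05, and each chromosome likewise over 23 chromosomes. Odds ratios are conditional maximum likelihood estimates with 95% intervals. The overlap of all 3 libraries was compared with 10000 random draws (seed 1) with equal weights, with weights by gene length, and with the number per chromosome and group of gene length (5 groups) kept. Lists were also compared with 10000 random lists matched on length (10 groups) or on chromosome and length (5 groups). Correlations across chromosomes used permutation tests with 100000 resamples. Chromosomes were further tested with Mantel-Haenszel odds ratios over 10 strata of gene length or of local gene spacing. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

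The tests were checked on simulated calls for the same 20056 genes. In 100 simulations of the list comparison, 95.2% of lists planted with an odds ratio of 4 and 96% of lists planted at 0 were recovered, and 1.12% of unplanted lists were called. The highest odds ratio of a list in the main comparison was 2.05, so recovery of differences of that size was not checked. Calls were drawn gene by gene, without the clustering of listed genes seen in the data. The share of unplanted lists called therefore does not carry over to clustered genes. In 20 simulations of the chromosome comparison, 100% of chromosomes planted with an odds ratio of 2 were recovered. Calls made to rise steadily with gene length alone gave 8.75 chromosomes past the threshold on average, and 0 once stratified by length. In the data the share listed rose and then fell with length. The simulation therefore checks the stratification and does not show how far length acts here. For the overlap of all 3 libraries, 2% of simulations with independent libraries fell below the threshold.

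Genes named in the text were DEK and CXCR2 and up to 4 members of each list, those in the most libraries first and then in alphabetical order. The parts of that rule that rank genes by peak score could not be applied. Comparisons planned on peak overlap, peak position and peak score were not run either, because the lists hold no peaks. Leaving out each library, other listing rules, each library on its own, other backgrounds, other naming rules and matching on length or chromosome were tried as well.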

Results

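DEK, a chromatin protein that binds DNA and is abundant in proliferating cells, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in MCF7 A-DCCs. MCF7 is an established, estrogen receptor-positive human breast cancer cell line, and the study's title concerns dormant cancer cells. The design asked where DEK sits in the genome of these cells. 3 DEK libraries formed 1 group, and 1 library of input DNA completed the series. For each DEK library the deposited values were a list of Ensembl gene identifiers with a peak, each present or absent. Read depth, peak positions and peak heights are therefore unknown here, and no values of the input library were analysed. The labels do not say whether the 3 libraries came from separate cultures, so their agreement may be technical. The p-values below compare genes or chromosomes with each other and do not measure the spread between cultures.

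Library 1 listed 3295 gene identifiers, library 2 listed 10128 and library 3 listed 4576. The mean was 6000 ± 3632 (SD, n = 3), and the longest list was 3.07 times the shortest. Of 10619 identifiers listed at least once, 2651 (24.96%) appeared in all 3 libraries, 2078 in 2 and 5890 in 1. Library 2 accounted for most of the single listings, because 5446 of its identifiers (53.8%) appeared in neither of the other libraries. The corresponding numbers were 193 (5.86%) for library 1 and 251 (5.49%) for library 3.

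**Figure D1:**
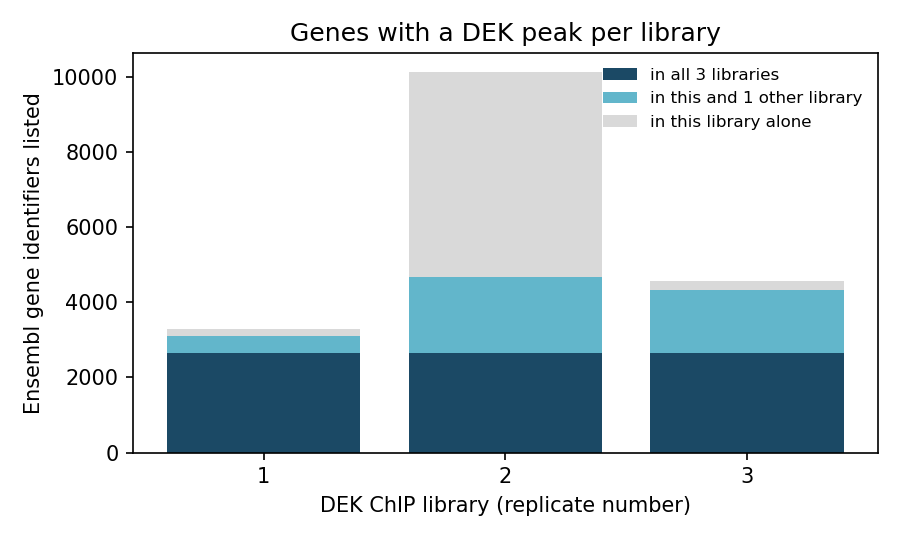
Ensembl gene identifiers listed (vertical axis) in each of the 3 DEK ChIP libraries (horizontal axis), split into those found in all 3 libraries, in 1 other library, or in that library alone. Each bar holds the same 2651 shared identifiers, and 5446 of the 10128 in library 2 were listed there alone.

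The shorter lists lay largely inside the longer ones. Libraries 1 and 2 shared 3055 identifiers, which were 92.7% of library 1. Libraries 2 and 3 shared 4278, which were 93.5% of library 3, and libraries 1 and 3 shared 2698, or 81.9% of library 1. Among 20056 protein-coding symbols, the overlap was 3.37 times chance for libraries 1 and 2, 5.93 times for libraries 1 and 3 and 3.40 times for libraries 2 and 3. A total of 1735 symbols were listed in all 3 libraries, against a mean of 83.1 for random sets of the same sizes (two-sided permutation p = 0.0002, the smallest that 10000 draws can give). Random sets weighted by gene length gave 668 on average, and sets that kept each library's make-up by chromosome and length gave 145, each with a permutation p of 0.0002. The weighted sets favour the longest genes. In the data the longest of 10 length groups had the lowest share listed (9.07%), so 668 is not a close model of these lists. Without library 1 the shared symbols numbered 2689. Against only the symbols listed in any library, the overlap of libraries 1 and 2 was 0.983 times chance and that of libraries 2 and 3 was 0.990 times chance, because library 2 then holds nearly all of the background. The overlap of libraries 1 and 3 was 1.73 times chance there.

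The 2969 protein-coding symbols listed in at least 2 libraries (14.8% of the background) were compared with 24 gene lists. Of these lists, 3 held fewer listed genes than the other genes did, and 21 did not pass the threshold on the adjusted p. At an unadjusted p below 0.05, 1 list was higher and 4 were lower by Fisher's exact test. Gene names rest on protein similarity, and of 89 named genes with a match 20 had an E-value above 1e-50. Of the genes named below these were AXIN1 (8.1e-13), DVL1 (1.82e-40), PIK3R2 (2.94e-10), AKT1 (5.38e-15), CDKN1C (4.98e-25), XRCC3 (4.48e-19), GAS6 (1.62e-19), COL1A1 (2.31e-21) and COL5A1 (2.94e-13), beside those marked where they appear. The names APC2, CHD2, PLK1 and BAK1 were each carried by 2 identifiers and KRT86 by 3, beside others marked where they appear.

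Genes of Wnt signalling, a pathway of cell fate and tissue renewal, had the highest share. Of 42 members, 11 (26.2%) were listed, against 14.8% of other genes, and all 11 were found in all 3 libraries. They included AXIN1 (ENSG00000103126), a scaffold of the beta-catenin destruction complex, APC2, the cytoplasmic transducer DVL1 (ENSG00000107404) and the receptor FZD9 (ENSG00000188763). The names of the remaining 7 were looked up after their values were seen: the co-receptor LRP5, the transcription factor TCF7 and the ligands WNT3, WNT3A, WNT4, WNT7B and WNT11. The odds ratio was 2.05 (95% interval 0.927 to 4.19) and did not pass the threshold (two-sided Fisher's exact test, adjusted p = 0.231). With the stricter demand of all 3 libraries the odds ratio was 3.76 (adjusted p = 0.0163 by Fisher's exact test), and it was 3.71 (adjusted p = 0.0184 by Fisher's exact test) without library 2. Against only the symbols listed in any library it was 1.07. That background is itself chosen by listing, so the value compares how often listed members recur between libraries. When matches to other organisms also named genes, 13 of 42 members were listed (odds ratio 2.38, Fisher's exact test adjusted p = 0.0822). Over all 15 alternatives the adjusted p ranged from 0.0139 to 1 by exact or permutation test.

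Of 35 genes of estrogen response and luminal identity, 9 (25.7%) were listed, with an odds ratio of 1.995 (95% interval 0.822 to 4.40) that did not pass (Fisher's exact test, adjusted p = 0.253). RARA (ENSG00000131759), a retinoic acid receptor, KDM4B (ENSG00000127663), a histone demethylase, and CELSR2 (ENSG00000143126), a cadherin, appeared in all 3 libraries. So did KRT8, a luminal keratin, but 7 identifiers carried that name, several of which can be processed copies of the gene. When listing in 1 library was enough, 19 of the 35 were listed and the odds ratio was 2.89 (Fisher's exact test, adjusted p = 0.0136), while the adjusted p over its 15 alternatives ranged from 0.00656 to 1 by exact or permutation test. Against only the symbols listed in any library the odds ratio was 0.872 (9 of 19 members). This too compares recurrence between libraries, because that background is chosen by listing.

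Growth factor, PI3K and MAPK signalling had 10 of 40 members listed (odds ratio 1.92, Fisher's exact test adjusted p = 0.253). Those in all 3 libraries included the receptors FGFR1 and FGFR3, the kinase AKT1 and the PI3K subunit PIK3R2. Chromatin regulators had 13 of 59 listed (22.0%, odds ratio 1.63, Fisher's exact test adjusted p = 0.277), among them the acetyl-lysine reader BRD4, the remodeller CHD2, the DNA methyltransferase DNMT3A and the deacetylase HDAC5, each in all 3 libraries. Glycolysis and lactate genes had 6 of 29 listed (20.7%, odds ratio 1.502, Fisher's exact test adjusted p = 0.513), with PKM, PDK2 and PFKFB4 in all 3 libraries. The name PKM rested on a weak match (E-value 2.85e-11), and the name GAPDH on 1 identifier with an E-value of 2.8e-40. Drug efflux and survival genes had 6 of 33 listed (18.2%, odds ratio 1.28, Fisher's exact test adjusted p = 0.621), including the transporter ABCC3 in all 3 libraries and the pro-apoptotic genes BAK1, BBC3 and BID in 2. The direction of this list was not stable, since its odds ratio was 0.330 with all 3 libraries required and 0.891, 0.324 and 0.908 without libraries 1, 2 and 3. Glycolysis was at 0.970 against only the symbols listed in any library, a background that is itself chosen by listing.

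Lists of cell division showed low shares that did not pass the threshold. G1/S genes had 2 of 34 listed (5.88%, odds ratio 0.359, Fisher's exact test adjusted p = 0.381), namely the kinase inhibitor CDKN1C in 3 libraries and the cyclin CCND3 in 2, while CCND1 and CDK4 were listed in library 2 alone. G2/M and mitosis genes had the same count and odds ratio, from PLK1 and from NEK2, whose name rested on a weak match (E-value 3.86e-07). DNA replication had 2 of 38 listed (5.26%, odds ratio 0.319, Fisher's exact test adjusted p = 0.253), the licensing factor CDT1 in 3 libraries and RPA1 in 2. DNA damage response and repair had 2 of 40 (odds ratio 0.302, Fisher's exact test adjusted p = 0.253), RAD51B and XRCC3, each in 2 libraries. Among p53 target genes 1 of 30 was listed, BBC3 (odds ratio 0.198, Fisher's exact test adjusted p = 0.253), and CDKN1A, BTG2 and DDB2 (a weak match, E-value 6.69e-17) were listed in library 2 alone. The direction of the p53 targets turned with the listing rule, to an odds ratio of 2.13 with at least 1 library (14 of 30) and 2.25 in library 2 alone. The size of the other differences also followed that rule. With at least 1 library the odds ratios were 0.874 for G1/S, 0.520 for G2/M, 0.867 for DNA replication and 0.428 for DNA damage response. None of these passed the threshold.

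Genes tied to tumour dormancy and quiescence had 3 of 38 listed (7.89%, odds ratio 0.493, 95% interval 0.0969 to 1.56), which did not differ from other genes past the threshold (Fisher's exact test, adjusted p = 0.496). GAS6, a ligand of TAM receptors, was named in all 3 libraries, its receptor TYRO3 and the tetraspanin CD82 in 2, and BMP7 in library 2 alone. The names GAS6 and CD82 were each carried by 2 identifiers. With symbols of a single identifier, 1 of the 38 dormancy genes was listed (odds ratio 0.179). With at least 1 library 10 of 38 were listed (odds ratio 0.867), and in library 2 alone the odds ratio was 0.917. The dormancy list passed the threshold in none of its 15 alternatives. Stemness and epithelial-mesenchymal transition genes had 3 of 34 listed (odds ratio 0.557, Fisher's exact test adjusted p = 0.529), with NOTCH1 (ENSG00000148400) and NOTCH3 (ENSG00000074181) in all 3 libraries and HES1, a Notch target, in 2. With at least 1 library the odds ratio of that list turned to 1.51. Immune, NF-kappaB and interferon genes had 4 of 42 listed (odds ratio 0.605, Fisher's exact test adjusted p = 0.534): IRF7 in 3 libraries, and IRF3, ISG15 and NFKB2 in 2. No identifier carried the name DEK in any library. CXCR2, a chemokine receptor, was also named by no identifier, although 1 naming rule that accepts matches to proteins of other organisms placed it in 2 libraries.

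Mitochondrial oxidative phosphorylation had 2 of 55 listed (3.64%, odds ratio 0.217, 95% interval 0.0256 to 0.823), CYC1 and UQCRC1 of complex III, both in all 3 libraries, with a Fisher's exact test adjusted p of 0.0785. This low share depended on the naming rule. When matches to other organisms also named genes, 6 of 55 were listed (odds ratio 0.648, Fisher's exact test adjusted p = 0.523). RNA splicing had 2 of 42 (odds ratio 0.287, Fisher's exact test adjusted p = 0.253), SRRM2 in 3 libraries and SF3A2 in 2. Ribosomal protein genes had 8 of 74 (10.8%, odds ratio 0.697, Fisher's exact test adjusted p = 0.513). The direction of this group followed the naming rule, since the odds ratio was 2.56 (Fisher's exact test, adjusted p = 0.00282) when matches to other organisms also named genes and 0.0906 (Fisher's exact test, adjusted p = 0.0104) when symbols carried by several identifiers were left out. RPL12, for instance, was carried by 5 identifiers and RPL17 by 3.

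The 3 lists past the threshold were all lower. None of 50 long neuronal genes was listed in at least 2 libraries (95% exact interval 0 to 7.11%; Fisher's exact test, adjusted p = 0.00599), and DPP6 and PTPRT were listed in library 2 alone. None of 54 replication-dependent histone genes was listed (95% exact interval 0 to 6.60%; Fisher's exact test, adjusted p = 0.00599). Near-identical histones share their best match, however, and of 14 identifiers with a histone H1 to H4 match 2 were in at least 2 libraries. Among 56 olfactory receptors, which act mainly in the sensing of odours, 1 was listed (odds ratio 0.104, 95% interval 0.00259 to 0.607, Fisher's exact test adjusted p = 0.0174). That 1 was OR13A1, whose identifier matched it weakly (E-value 8.83e-15). The differences stayed in the same direction in the settings that follow, with histones and neuronal genes at 0 and olfactory receptors at odds ratios of 0.165 to 0.192, or 1 against 8.33 genes when matched on length. The calls, however, were lost without library 2 or without library 3, when listing in all 3 libraries was required, and against random lists matched on gene length, where the permutation adjusted p was 0.118 for the neuronal genes, 0.0696 for the histones and 0.0624 for the olfactory receptors. Against random lists matched on both chromosome and length the call of the olfactory receptors was kept (1 against 9.33 genes, permutation adjusted p = 0.0048). Those of the neuronal genes (0 against 4.97, permutation adjusted p = 0.101) and of the histones (0 against 1.98, permutation adjusted p = 0.384) were not.

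The remaining control lists did not pass the threshold. Keratin-associated and hair keratin genes, also silent in most tissues, had 8 of 38 listed (21.1%, odds ratio 1.54, Fisher's exact test adjusted p = 0.410), with KRT74 and KRT86 in all 3 libraries. Split after the values were seen, 8 of 17 hair keratins and 0 of 21 keratin-associated proteins were listed. Genes of regions amplified in MCF7 had 7 of 37 listed (18.9%, odds ratio 1.34, Fisher's exact test adjusted p = 0.529), PREX1 and TBX2 in all 3 libraries. Fibroblast and endothelial markers had 5 of 23 (odds ratio 1.60, Fisher's exact test adjusted p = 0.496), with COL1A1, COL5A1 and PDGFRB in all 3 libraries. Leukocyte markers had 1 of 20, ITGAX (odds ratio 0.303, Fisher's exact test adjusted p = 0.496). Of these lists, 3 changed direction with the listing rule: with all 3 libraries required the odds ratio was 0.586 for the joint keratin list and 0.603 for the amplicon genes, and with at least 1 library it was 1.62 for the leukocyte markers.

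**Figure D2:**
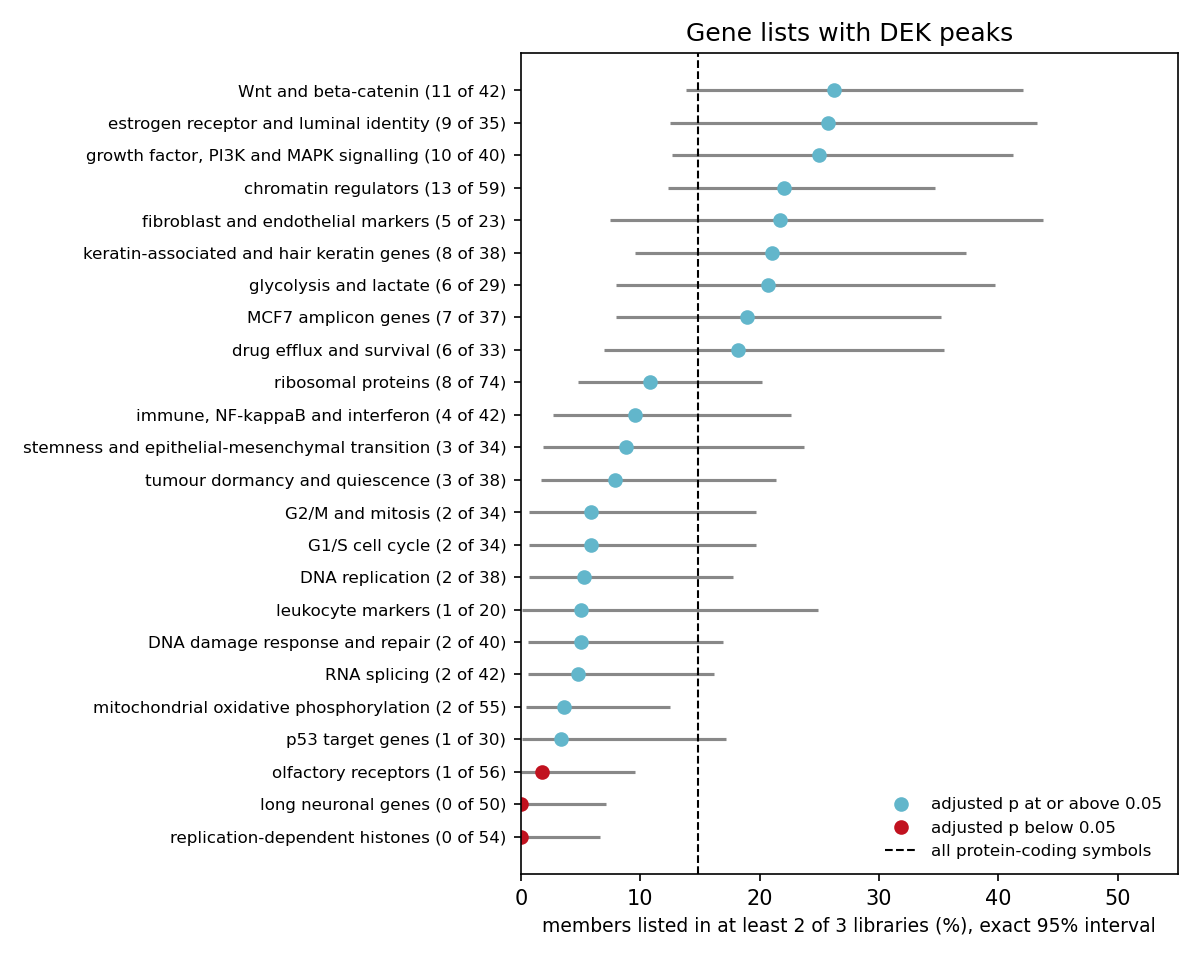
Percent of each gene list's members listed in at least 2 of 3 DEK libraries (horizontal axis), with exact 95% binomial intervals as lines and the counts beside each name. The dashed line marks the 14.8% of all protein-coding symbols, and the red points are the 3 lists with an adjusted p below 0.05.

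Listed genes were spread unevenly over the chromosomes. On chromosome 22, 29.9% of 451 protein-coding symbols were listed (95% exact interval 25.7 to 34.4%), on chromosome 16, 29.0% of 854, and on chromosome 17, 26.8% of 1169. The lowest shares were 2.71% of 848 on chromosome X (95% exact interval 1.73 to 4.04%), 2.96% of 270 on chromosome 18 and 4.44% of 338 on chromosome 13. Odds ratios against all other genes were 2.53 for chromosome 22 (Fisher's exact test, adjusted p = 5.07e-16) and 0.154 for chromosome X (Fisher's exact test, adjusted p = 1.29e-31). In all, 18 of 23 chromosomes passed the threshold by Fisher's exact test, 7 above the other genes (9, 11, 16, 17, 19, 20 and 22) and 11 below (2, 3, 4, 5, 6, 7, 10, 12, 13, 18 and X). Once stratified by local gene density, 11 of the 18 stayed past the threshold, 5 above (9, 16, 17, 20 and 22) and 6 below (4, 6, 12, 13, 18 and X). Some of these lay nearer to the other genes, with odds ratios of 0.424 in place of 0.174 for chromosome 18, 0.530 in place of 0.264 for chromosome 13 and 0.634 in place of 0.389 for chromosome 4. The calls of chromosomes 2, 3, 5, 7, 10, 11 and 19 were lost, and chromosome 19 turned from an odds ratio of 1.62 to 0.883 and chromosome 10 from 0.767 to 1.06. The calls for chromosomes 7, 10 and 12 were also lost when some replicates were left out, and the odds ratio of chromosome 7 turned to 1.01 without library 2.

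The 3 libraries gave a similar order of chromosomes. Across the 23 chromosomes, which are not independent replicates, the share of listed symbols in libraries 1 and 2 had a Pearson r of 0.932 and a Spearman rho of 0.925. For libraries 1 and 3 these were 0.982 and 0.972, and for libraries 2 and 3 they were 0.965 and 0.926. Each of the 3 pairs had a two-sided permutation p of 2e-05 for r and for rho, raw and adjusted, the smallest that 100000 resamples can give. Without the 2 chromosomes farthest from the median, r was 0.918, 0.973 and 0.960 in the same order.

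**Figure D3:**
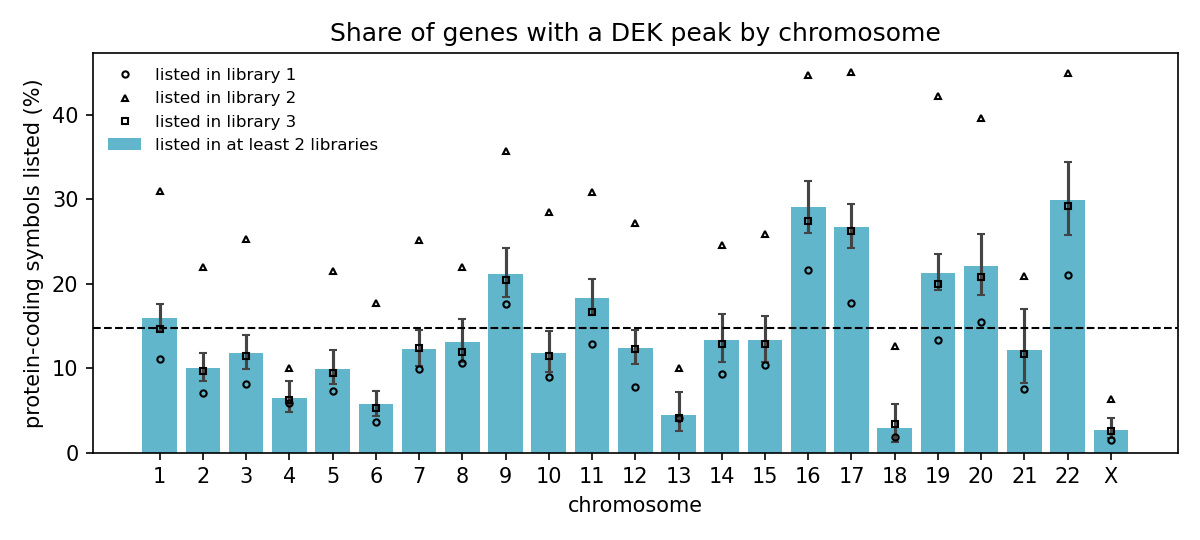
Percent of protein-coding symbols listed (vertical axis) on each chromosome (horizontal axis). Bars give symbols listed in at least 2 libraries with exact 95% binomial intervals, open symbols give each library, and the dashed line marks 14.8%; the bars run from 2.71% on chromosome X to 29.9% on chromosome 22.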

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

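Some identifiers outside the comparisons of named genes were also listed in all 3 libraries. Of 2485 identifiers with no Swiss-Prot match, 505 (20.3%) were in all 3 libraries, against 27.3% of identifiers with a human match and symbol. The same held for 158 of 842 identifiers (18.8%) matched to a protein of another organism and for 47 of 187 (25.1%) matched to a human protein without a symbol. They drew attention because no named-gene comparison uses them. No input or control list was analysed, so a background level cannot be set beside these counts. With groups of 3 libraries, no single library was tested for standing apart from the others.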

How the results depend on the processing

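Alternatives on naming, matching on chromosome, stratification by length or local gene density, provisional symbols and the demand of all 3 libraries for chromosomes were chosen after the data were seen. For chromosomes, 186 of 206 alternative values kept their direction and side of the threshold. Stratified by local gene density, 5 chromosomes were above the other genes and 6 below, 11 in all, and chromosomes 1, 8, 10 and 19 turned to odds ratios of 0.970, 1.22, 1.06 and 0.883, none past the threshold. In every other setting 7 were above and 9 to 11 below. Among lists, 306 of 359 values kept their direction and side of the threshold, and among named genes 239 of 273 library counts stayed within 1.5 times the main count; 20 named genes moved with matches limited to E-values of 1e-50, 12 with symbols of a single identifier and 2 with names from other organisms. The cause was not tested unless stated. No depth is known, so whether low counts reflect shallow sequencing stays open.

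Identifiers in all libraries numbered 2698 to 4278 and symbols 1760 to 2689 without 1 replicate, since fewer libraries had to agree. Against symbols in any library the overlap over chance was 0.983 for libraries 1 and 2 and 0.990 for libraries 2 and 3, by construction of that background. For libraries 1 and 3 the overlap was 1.73 times chance. The number of lists past the threshold, 3 in the main analysis (0 higher, 3 lower), was 5 (2 higher) with at least 1 library, 1 (1 higher, 0 lower) with all 3 libraries, 0 to 3 without 1 replicate (0 to 1 higher, 0 to 3 lower), 0 in library 1 alone, 5 (2 higher) in library 2 alone, 1 (lower) against symbols in any library, 0 matched on length and 1 (lower) matched on chromosome and length. Names from other organisms made 1 list higher.

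With at least 1 library the odds ratio was 2.89 for the estrogen and luminal list, 2.43 for Wnt, 1.51 for stemness, 2.13 for p53 targets and 1.62 for leukocyte markers, the last 3 turning above 1 without passing. In library 2 alone these were 3.06, 2.57, 1.40, 2.25 and 1.71. With all 3 libraries Wnt was 3.76, drug efflux 0.330, amplicon genes 0.603, the list of keratin-associated and hair keratin genes 0.586, olfactory receptors 0.192, and histones and neuronal genes 0, the last 3 no longer past the threshold. Without 1 replicate Wnt ranged from 2.30 to 3.71, drug efflux from 0.324 to 0.908, amplicon genes from 0.518 to 1.51, the joint keratin list from 0.577 to 1.46, olfactory receptors from 0.117 to 0.189, and histones and neuronal genes stayed at 0. In library 1 alone drug efflux was 0.852, amplicon genes 0.752, the joint keratin list 0.730, olfactory receptors 0.155, histones 0.160 and neuronal genes 0, the last 3 without passing, and in library 3 alone drug efflux was 0.841. Against symbols in any library the estrogen and luminal list was 0.872, glycolysis 0.970, ribosomal proteins 1.55 and drug efflux 0.646. In that setting p53 targets were at 0.0743 (past the threshold), and histones and neuronal genes at 0 without passing. That background keeps only symbols already listed, so these values compare recurrence between libraries. Of the 14 p53 targets in it, 13 were listed in 1 library only. Ribosomal proteins were 2.56 with names from other organisms and 0.0906 with symbols of a single identifier, both past the threshold; the second leaves out, by construction, names that several identifiers share, and the cause of the first was not tested. Matched on length, listed over expected genes were 0.120 for olfactory receptors and 0 for histones and neuronal genes, none past the threshold; matched on chromosome and length, the amplicon ratio was 0.782 and histones and neuronal genes were at 0 without passing. Chromosome 7 had odds ratios of 0.843 to 1.01 without 1 replicate and 1.01 with all 3 libraries, and chromosome 8, which passed in no setting, 0.867 to 1.03 and 1.04. No paired analysis was possible because the libraries form 1 group. Comparisons on peak score, promoter peaks, peak overlap, library size by score and chromosome length were not run, because the lists hold no peaks.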

Other observations

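Gene families defined by the letters that begin a symbol were compared in the same way, a comparison chosen after the data were seen. A first run that kept provisional symbols in the background called more families, and the run without them is given, because no match can name those symbols. Of 147 such families with at least 15 members, 5 were listed more often and 5 less often than other genes by Fisher's exact test. Semaphorins (SEMA), secreted and membrane guidance proteins, had 10 of 20 listed (odds ratio 5.55, Fisher's exact test adjusted p = 0.00861), and solute carriers (SLC) had 85 of 386 (odds ratio 1.58, Fisher's exact test adjusted p = 0.0108). Both also exceeded random genes of the same chromosomes and length, which gave 2.46 and 58.7 listed genes on average (permutation adjusted p = 0.00588 and 0.0110), and both kept the call when only matches with an E-value of at most 1e-50 gave names (Fisher's exact test adjusted p = 0.00153 and 0.0254). Wnt ligands had 9 of 19 (Fisher's exact test adjusted p = 0.0205) and kept the call with strict names (Fisher's exact test adjusted p = 0.00509). The excess remained but was no longer past the threshold against matched genes (9 against 3.28 on average, permutation adjusted p = 0.0676) and when all 3 libraries were required (odds ratio 3.64, Fisher's exact test adjusted p = 0.240). Among the 9, WNT3, WNT3A, WNT4, WNT7B and WNT11 are also listed members of the Wnt signalling list above. The family is therefore not separate support for that list.

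Collagens (COL) had 21 of 44 listed (odds ratio 5.08, Fisher's exact test adjusted p = 1.96e-05), and kept the call against matched genes (4.89 on average, permutation adjusted p = 0.00588), with all 3 libraries required (odds ratio 4.78, Fisher's exact test adjusted p = 0.000857) and with at least 1 library (Fisher's exact test adjusted p = 0.00625). With strict names, however, 7 of 44 remained and the odds ratio was 1.36 (Fisher's exact test adjusted p = 0.901). Mucins (MUC) had 8 of 18 (Fisher's exact test adjusted p = 0.0454) and all 8 were in all 3 libraries, where the odds ratio was 8.17 (Fisher's exact test adjusted p = 0.00286). With strict names the odds ratio was 0.899, and the call was also lost with at least 1 library (Fisher's exact test adjusted p = 0.158) and against matched genes (permutation adjusted p = 0.0857). With strict names neither of these 2 families kept its call. The limit could only remove listed members, while unlisted members stayed in each family, so a listed count could only fall or stay. The E-value limit was not tested as a measure of whether a name is right. Whether the names it removed were wrong therefore stays open.

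Families listed less often were olfactory receptors (4 of 392, odds ratio 0.0558, Fisher's exact test adjusted p = 8.06e-21), zinc finger genes named ZNF (21 of 517, odds ratio 0.229, Fisher's exact test adjusted p = 1.14e-14), keratin-associated proteins (2 of 94, odds ratio 0.120, Fisher's exact test adjusted p = 0.00149), beta-defensins (0 of 39, Fisher's exact test adjusted p = 0.0454) and ubiquitin-specific proteases (3 of 77, odds ratio 0.223, Fisher's exact test adjusted p = 0.0436). The last 2 were no longer past the threshold when all 3 libraries were required (Fisher's exact test adjusted p = 0.375 for both) and with strict names (Fisher's exact test adjusted p = 0.139 and 0.216), although the odds ratios stayed similar, at 0 for the defensins and at 0.271 and 0.291 for the proteases. The first 4 stayed below random genes of the same chromosomes and length; for ZNF genes these gave 99.6 listed genes on average (permutation adjusted p = 0.00588). The proteases did not (permutation adjusted p = 0.158). Neither Fisher's exact test nor the matched random genes keep neighbouring genes together. For families whose members neighbour each other, these p-values can therefore be too small. By gene length, the share listed was 9.52% in the shortest of 10 groups of genes, 18.5% in group 5 and 9.07% in the longest.

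The uneven share of listed genes over chromosomes was set against 3 technical explanations. The copy number test and the separate reading of chromosomes by local gene density were chosen after the result was seen. The stratifications were added after the files were seen, with bounds set before their outcome was known. Gene length argued against itself as the whole cause, because 18 of 18 chromosomes stayed past the threshold in the same direction when stratified by length. Stratified by local gene density, 11 of 18 stayed past it in the same direction (4, 6, 9, 12, 13, 16, 17, 18, 20, 22 and X). By the bounds set beforehand this count could not decide on density. In the separate reading, density as measured did not remove the calls of those 11, although chromosomes 4, 13 and 18 moved nearer to the other genes. For the other 7 density stays open. Copy number cannot be told apart from other causes. Genes of MCF7 amplicons were listed 0.782 times as often as random genes of the same chromosomes and length (7 against 8.95 genes, permutation p = 0.586). Because these random genes keep the chromosome, the test cannot show whether copy number of whole chromosomes shapes the pattern. GC content was not tested, because no genome sequence was used, and the design gives no biological contrast.

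The longer list of library 2 was tested for the same signal called more deeply against genes listed evenly over the genome. The bounds of this test were set beforehand. For each chromosome, the share listed in library 2 alone was taken over the symbols not listed in at least 2 libraries. Across 23 chromosomes that share followed the share of all symbols listed in at least 2 libraries. Pearson r was 0.848 and Spearman rho was 0.825 (permutation p = 2e-05 for both, the smallest possible), and r was 0.854 without the 2 chromosomes farthest from the median. Genes listed evenly over the genome would have given no such relation. Background that follows the same chromosomes could give it too. The test therefore argues against an even spread and cannot show that the signal is the same. Whether deeper sequencing, a lower threshold, a stronger precipitation or such background lies behind the longer list stays open. Depth is unknown, and no values of the input library were analysed.

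Listed genes lay next to each other in gene order. Adjacent pairs of listed genes numbered 1274, against a mean of 540 in 1000 shuffles within chromosomes and 598 in the highest. The excess at a distance of 10 genes was 56.2% of that of adjacent genes (946 pairs, against 595 in the highest shuffle). At a distance of 50 genes the excess was 16.8%. By bounds set beforehand, this argues against a peak shared by adjacent genes as the whole cause and is what domains of many genes would give. The shuffles kept neither local gene density nor gene length. A regional trend in either could give the same excess, as could a rule that assigns a peak to every gene in a window. A separate hypothesis was that genes near chromosome ends are listed more often. Of the 1998 genes in the outermost 5% at each end, 26.4% were listed, against 13.6% of the others. Within-chromosome permutations gave a mean of 14.9% (permutation p = 2e-05, the smallest that 100000 permutations can give). A first run with fewer permutations had the same outcome. These permutations also kept neither local gene density nor gene length, so either could lie behind the difference.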
